A study of Homo sapiens with 16 samples.

How the data were processed

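Expression was measured in total RNA from 2 human colorectal carcinoma cell lines, DLD1 and HCT116, each in 2 derivatives with a different PIK3CA allele left, grown with or without glutamine for 24 h. Per the labels' protocols, the medium was DMEM with 10% dialyzed fetal bovine serum and the biotin-labelled targets were made with the Affymetrix whole-transcript protocol. The labels give 8 groups of 2 biological replicates, 16 arrays, and every column of values was matched to its sample.

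The deposited table holds 1 intensity for each of 53617 probe sets on each array. The values were linear, with array medians from 3.57 to 3.70, upper quartiles from 19.9 to 22.7, 99th percentiles from 1538 to 1716 and maxima from 10869 to 11654. The arrays had near-equal distributions, and the method and software of any normalization are not given in the sources used here. The log2 of each intensity was taken here, with no pseudocount and no further normalization.

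Gene symbols came from the table of probe sets and genes that goes with the deposited values. Of its 25713 probe sets 23871 had exactly 1 symbol and 1842 several, and 27904 probe sets of the value table had none. By Entrez identifier 88 symbols were brought to their current form with a RefSeq gene table of assembly GRCh38.p14, and 2 were kept as given. Only probe sets with 1 symbol were used, and for the 631 genes with several the probe set with the highest mean over the 16 arrays, which gave 22395 genes. Genes in the upper 70% of mean log2 intensity were tested, 15676 in all, with a lowest mean of 1.65. The 29746 probe sets with no or several symbols entered no comparison of the report.

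Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of 8 group means over the 16 arrays, with 8 residual degrees of freedom and 2.49 prior ones. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes were called. The 14 contrasts were glutamine withdrawal in each derivative, its average and its difference between the lines, Mut against WT with glutamine in each line and on average, the same without glutamine in each line, and the interaction of genotype and glutamine in each line and on average. Errors printed with log2 changes are limma's SE, and folds are 2 to the power of the absolute log2 change. Overlaps were counted per direction beside the count that independent calls would give, and no contrasts compared in an overlap share an array. All contrasts share 1 spread per gene from the fit, so a gene with a small spread is more readily called in each of them. For the overlap of Mut against WT calls a two-sided Fisher's exact test was run, which treats genes as independent.

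Before the data were examined, 27 gene lists, the contrasts, the tests, the alternatives and the rule for naming genes were fixed. The lists cover the amino acid response (ATF4 targets), aminoacyl-tRNA synthetases, glutamine and glutamate metabolism, serine, glycine and folate one-carbon metabolism, nucleotide synthesis, cholesterol and fatty acid synthesis, DNA replication, mitosis, and p53, NRF2, FOXO and Wnt targets. They also cover endoplasmic reticulum chaperones, hypoxia and glycolysis, the respiratory chain, ribosome biogenesis, lysosome and autophagy, ERK pathway output, colon epithelial differentiation, mesenchymal genes, NF-kB and chemokines, interferon-stimulated genes, apoptosis regulators, and markers of fibroblasts, leukocytes, and normal colon stroma and endothelium. Lists share members: 6 serine and one-carbon genes (PHGDH, PSAT1, PSPH, SHMT2, MTHFD2 and ALDH1L2) are also in the amino acid response list, and SLC7A11 is in that list and among the NRF2 targets. Of 569 list symbols 518 had a probe set of their own, and the other 51 were not analysed here. Lists with at least 8 tested members, 24 in all, were tested with camera at its preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Members that passed were counted with p adjusted over all genes and over the list alone.

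GLUL, ASNS and CXCL8 were always named. Named in each contrast were the 8 largest rises and falls among called genes (for contrasts of 2 groups only genes whose arrays did not overlap). For each list up to 4 called members with the smallest adjusted p in the direction of most called members and 1 in the other direction were named. For each overlap it was the 8 genes with the largest change in the contrast where each changed least. The text gives a part of these genes. Genes of families with near-identical copies are given as uncertain.

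The alternatives were no filter on dim genes, genes above the median of mean level, quantile normalization, shifting each array to the same median, the mean of a gene's probe sets, and a replicate block over all arrays or within each line. Others were eBayes with trend and robust, a 2-fold minimum, each line fitted separately, and leaving out each array in turn. The fit and the list test were tested on simulated data of 15676 genes. For glutamine withdrawal in DLD1 Mut cells 29.9% of genes changed by 0.5 log2, 65.7% of those changed by 1 and 98.5% of those changed by 2 were recovered, with 5.80% false calls. For Mut against WT with glutamine in HCT116 these shares were 16.4%, 67.2% and 92.4%, with 1.70% false calls. For the interaction in DLD1 they were 3%, 32.8% and 83.3%, with 7.10% false calls. A list of 20 members shifted by 0.4 was called (camera, adjusted p = 8.27e-18), and 0 of 23 others were. Only 66 or 67 genes were changed at each size. In the real data withdrawal in DLD1 Mut cells called 5268 genes, and with so many the Benjamini-Hochberg cutoff is laxer. The shares recovered thus do not carry over to that contrast. The genes were simulated independently of each other, so the list test was not tried on correlated members. Counts of other splits of the arrays used contrasts averaged over lines, since single contrasts hold 2 arrays against 2. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.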

Results

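Expression was measured on Affymetrix whole-transcript arrays in DLD1 and HCT116, established human colorectal carcinoma cell lines, each as a pair of derivatives that differ in PIK3CA, the gene of the p110-alpha catalytic subunit of phosphoinositide 3-kinase. In the derivative called Mut the wild-type allele had been knocked out, so that the mutant allele remained, and in the derivative called WT the mutant allele had been knocked out. Each of the 4 derivatives was cultured for 24 h with or without glutamine in medium with 10% dialyzed serum, which gave 8 groups of 2 biological replicates and 16 arrays in all. Median intensities lay between 3.57 and 3.70 and upper quartiles between 19.9 and 22.7 on every array. Replicates of a group correlated at r = 0.989 to 0.992 across genes, which are not independent replicates, and the median difference between them was 0.14 to 0.17 on the log2 scale. The first principal component held 60.4% of the variance and separated the cell lines, the next 14.8% and separated the arrays by glutamine. Markers of fibroblasts, leukocytes, and normal colon stroma and endothelium had only 5, 4 and 6 members bright enough to test, and on average over the 4 derivatives glutamine withdrawal raised 1, 1 and 0 of them and lowered 0, 0 and 0. PIK3CA itself and GPT2 had no probe set named for them alone and were not analysed here. Values in parentheses after a gene are log2 changes ± SE from limma, with 2 arrays in each group.

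The comparisons with and without glutamine ask which genes respond to its withdrawal in each derivative. Averaged over the 4 derivatives, target genes of ATF4, the transcription factor of the amino acid response, rose, while genes of DNA replication, nucleotide synthesis and cholesterol synthesis fell. DDIT3, a stress-induced transcription factor that was called in all 4 derivatives, rose 7.65-fold (log2 change 2.94 ± 0.17, 8 against 8 arrays, adjusted p = 1.96e-07). With the mean of its probe sets in place of the brightest, the log2 change of DDIT3 was 1.62 on average, 1.81 in DLD1 WT and 1.65 in HCT116 WT cells, each still called. PPP1R15A, which directs dephosphorylation of the translation factor eIF2-alpha, rose 6.83-fold (log2 change 2.77 ± 0.06), and the stress-induced regulator of translation NIBAN1 8.51-fold (log2 change 3.09 ± 0.11). INSIG1, which holds the sterol regulator SREBP in the endoplasmic reticulum, had a log2 change of -2.45 ± 0.09, and the replicative helicase subunit GINS2 one of -2.03 ± 0.06. Among the 36 tested members of the amino acid response list, 28 rose, 1 fell and 7 were not called (camera, adjusted p = 1.59e-11; 29 and 1 adjusted over the list alone). They included the leucine sensor SESN2 (2.32 ± 0.06), the mTORC1 inhibitor DDIT4 (2.08 ± 0.07) and the pseudokinase TRIB3 (1.51 ± 0.05), and the member that fell was the proline synthesis enzyme ALDH18A1 (-0.62 ± 0.04). All 29 tested genes of DNA replication fell on average (adjusted p = 3.27e-19; 29 adjusted over the list alone), among them the DNA ligase LIG1 (-1.40 ± 0.05), the helicase subunit MCM4 (-1.21 ± 0.04) and cyclin E1, CCNE1 (-1.34 ± 0.05). Of 20 nucleotide synthesis genes 18 fell and 0 rose (adjusted p = 9.28e-11; 19 fell adjusted over the list alone), including thymidylate synthase, TYMS (-1.30 ± 0.05), and the purine synthesis enzyme PAICS (-0.92 ± 0.04). Of 18 cholesterol synthesis genes 17 fell (adjusted p = 2.15e-09; 17 adjusted over the list alone), among them DHCR7 (-1.96 ± 0.05) and SQLE (-1.69 ± 0.06), which encode its last reductase and squalene epoxidase, and 1, the mevalonate pathway kinase PMVK (0.35 ± 0.08), rose. ERK pathway output genes rose in 13 of 21 cases and fell in 1 (adjusted p = 9.06e-05; 14 and 2 adjusted over the list alone), with the receptor EPHA2 (1.24 ± 0.05) and the MAP kinase phosphatase DUSP5 (1.48 ± 0.07) among them. The calls of these 5 lists held with an estimated correlation (adjusted p = 0.00102, 0.000627, 0.00354, 0.0302 and 0.0186, in the order given).

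Genes that use glutamine or glutamate moved both ways on average: of 20 tested, 12 fell and 3 rose (adjusted p = 0.00379, and adjusted p = 0.0673 with an estimated correlation; 12 and 3 adjusted over the list alone). The mitochondrial aspartate aminotransferase GOT2 (-0.78 ± 0.04) and the glutamine-dependent enzymes CTPS1 (-1.03 ± 0.07) and PFAS (-0.70 ± 0.06) fell, while the cytosolic aspartate aminotransferase GOT1 (0.97 ± 0.04) rose. Glutamine synthetase, GLUL, fell in HCT116 WT cells (-0.78 ± 0.21, adjusted p = 0.0258) and was not called in HCT116 Mut (-0.52 ± 0.21), DLD1 Mut (-0.05 ± 0.21) or DLD1 WT cells (-0.26 ± 0.21). The call of GLUL was lost without replicate 1 or 2 of HCT116 WT cells with glutamine (adjusted p = 0.126 and 0.0700) or replicate 1 without it (adjusted p = 0.184), and with HCT116 fitted alone (adjusted p = 0.101). Without HCT116 WT replicate 1 without glutamine, GLUL was at -0.46 in WT and -0.52 in Mut cells, so which value is larger rests on 1 array, and the Mut value ranged from -0.75 to -0.30 with 1 array left out. GLUL was called in HCT116 Mut cells when their replicate 2 without glutamine (adjusted p = 0.0486) or HCT116 WT replicate 1 or 2 without glutamine (adjusted p = 0.0387 for each) was left out. The chemokine CXCL8 rose in HCT116 Mut cells (0.83 ± 0.18, adjusted p = 0.00512) and was not called in the other 3 derivatives. CXCL8 was not among the genes above the median of mean level. Over the 4 derivatives 555 genes rose in all and 576 fell in all, where independent calls would give 6.25 and 5.67. With each line fitted separately 713 genes were shared by the 4, against 1131. The 8 shared genes with the largest change in the derivative where each changed least were DDIT3, BHLHE41 (2.73 ± 0.08), PPP1R15A, KRT80 (2.57 ± 0.09), SESN2, DHCR7, LURAP1L (2.63 ± 0.11) and the histone gene H2BC14. The value of H2BC14 (-2.56 ± 0.09) is uncertain because its family has near-identical copies.

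In DLD1 cells amino acid response genes rose and Wnt target genes fell. In DLD1 Mut cells NIBAN1 (3.67 ± 0.23), PPP1R15A (3.18 ± 0.11) and the circadian repressor BHLHE41 (3.17 ± 0.15) rose, and the immune receptor SLAMF6 (-4.34 ± 0.30) and the hyaluronan-degrading protein CEMIP (-3.16 ± 0.20) fell. In DLD1 WT cells the largest rises were NIBAN1 (4.86 ± 0.23), DDIT4 (4.05 ± 0.13), the monocarboxylate transporter SLC16A4 (3.41 ± 0.31), DDIT3 (3.40 ± 0.33), the stress ligand ULBP1 (3.33 ± 0.22) and the thioredoxin-binding protein TXNIP (3.29 ± 0.25). There SLAMF6 (-3.76 ± 0.30), CEMIP (-2.93 ± 0.20) and the receptor kinase KIT (-2.89 ± 0.30) fell. Asparagine synthetase, ASNS, which uses glutamine as its nitrogen donor, rose 2.24-fold in Mut (1.16 ± 0.10) and 4.86-fold in WT cells (2.28 ± 0.10). In the amino acid response list 24 of 36 genes rose and 1 fell in Mut cells (median 0.70, adjusted p = 4.41e-09), and 32 rose and 1 fell in WT cells (median 1.28, adjusted p = 3.64e-22). Adjusted over the list alone, 25 and 33 rose. Of 16 Wnt targets 11 fell in Mut and 12 in WT cells, and none rose (adjusted p = 5.87e-05 and 2.87e-07; 12 and 12 adjusted over the list alone). They included the intestinal stem cell factor ASCL2 (-2.20 ± 0.20) and the hyaluronan receptor CD44 (-1.84 ± 0.16) in Mut and the stem cell receptor LGR5 (-2.66 ± 0.31) and the feedback inhibitor AXIN2 (-1.76 ± 0.21) in WT cells. DNA replication genes fell in 28 of 29 cases in Mut and 22 in WT cells, where 1 rose (adjusted p = 7.53e-18 and 7.69e-09). Cholesterol synthesis genes fell in 13 and 14 of 18 cases (adjusted p = 3.16e-08 and 9.31e-12). With an estimated correlation the adjusted p in Mut and WT cells was 0.00241 and 0.000165 for the amino acid response, 0.0222 and 0.0081 for Wnt targets, 0.000822 and 0.00584 for DNA replication and 0.0479 and 0.0147 for cholesterol synthesis. In all, 5268 of 15676 genes passed in Mut cells (2636 rose, 2632 fell) and 4235 in WT cells (2202 rose, 2033 fell).

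**Figure D1:**
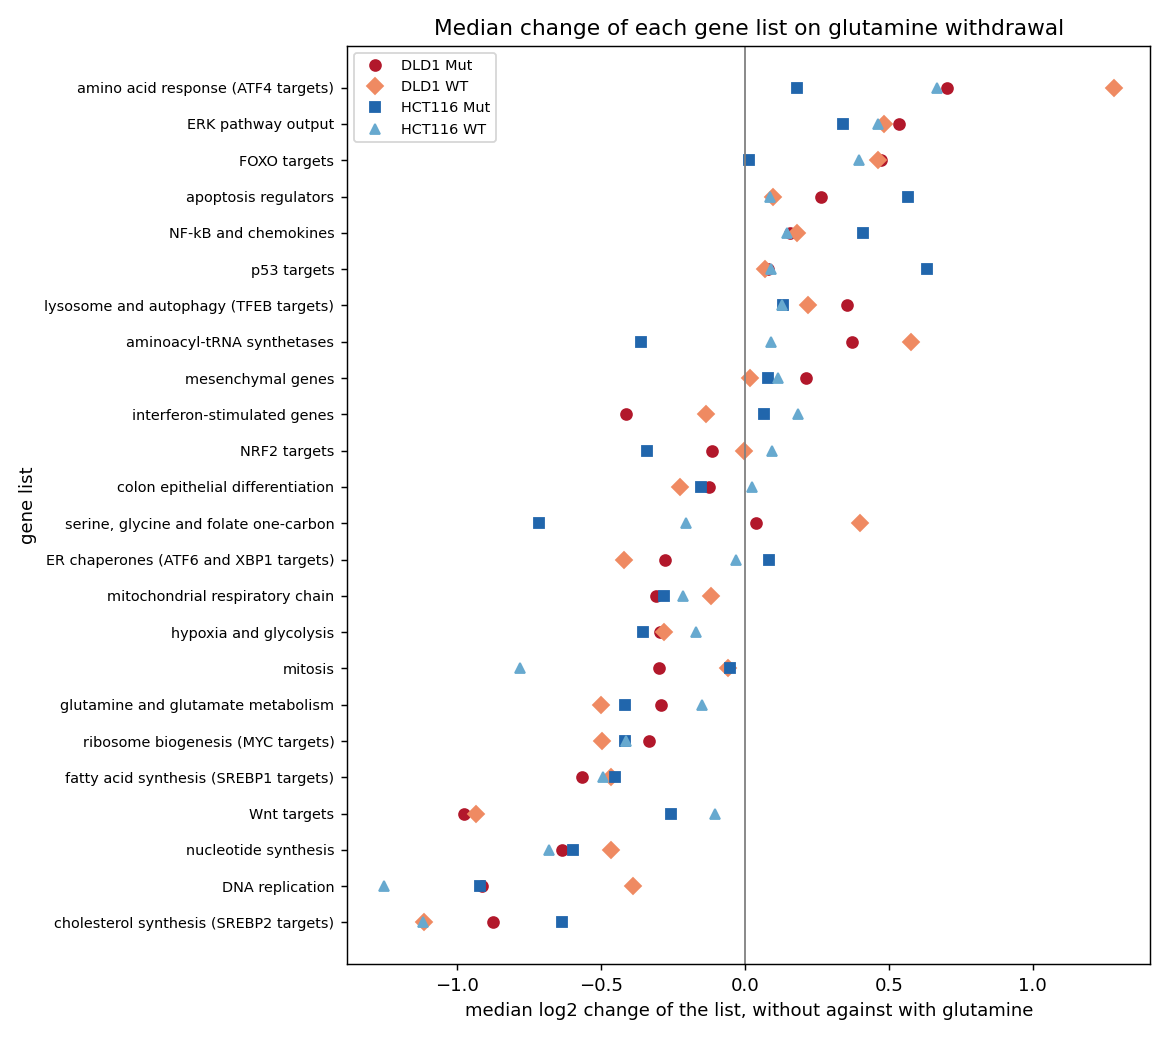
Median log2 change on glutamine withdrawal (x axis, without against with glutamine) of each of the 24 gene lists with at least 8 tested members (y axis) in DLD1 Mut, DLD1 WT, HCT116 Mut and HCT116 WT cells, 1 symbol per derivative. The amino acid response median was 1.28 in DLD1 WT and 0.18 in HCT116 Mut cells, and the DNA replication median lay between -1.25 and -0.39.

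In HCT116 Mut cells SNAI2, a repressor of epithelial genes, had the largest rise, 36.4-fold (5.18 ± 0.25, adjusted p = 7.73e-07). Other large rises were those of the keratin KRT80 (3.57 ± 0.17), the transcription factors ETS1 (3.50 ± 0.16) and JUN (3.30 ± 0.10) and the uridine phosphorylase UPP1 (3.46 ± 0.23). The creatine synthesis enzyme GAMT (-2.87 ± 0.24), the ligand WNT16 (-2.81 ± 0.34) and the channel subunit LRRC26 (-3.01 ± 0.20) fell. ASNS fell (-0.71 ± 0.10), as did the serine synthesis enzymes PSAT1 (-1.27 ± 0.09) and PHGDH (-1.24 ± 0.09). In the amino acid response list 14 genes rose, with PPP1R15A (2.93 ± 0.11) and ATF3 (1.95 ± 0.26) among them, 11 fell and 11 were not called, and the list as a whole was not called (adjusted p = 0.268). Of 20 p53 target genes 14 rose and 1 fell (adjusted p = 2.5e-06, and 0.0168 with an estimated correlation; 14 and 1 adjusted over the list alone), including the cell cycle inhibitor CDKN1A (1.40 ± 0.15) and the growth arrest gene GADD45A (2.30 ± 0.09). Of 19 NRF2 targets 11 fell and 4 rose (adjusted p = 0.003, and 0.0275 with an estimated correlation), with glutathione reductase, GSR (-1.42 ± 0.08), and transketolase, TKT (-1.57 ± 0.09), among those that fell. DNA replication genes fell in 27 of 29 cases, among them MCM5 (-1.53 ± 0.09), and mitosis genes went both ways, with 6 higher, such as UBE2C (0.60 ± 0.09), and 6 lower. In all 5159 genes passed (2574 rose, 2585 fell).

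In HCT116 WT cells DDIT3 (3.13 ± 0.33), the adaptor LURAP1L (3.82 ± 0.23) and the testis chaperone CLGN (2.83 ± 0.39) rose and INSIG1 (-2.93 ± 0.17) fell, as did the synaptic protein NRGN (-2.38 ± 0.24). Amino acid response genes rose in 24 of 36 cases and 1 fell (median 0.67, adjusted p = 6e-14). They included TRIB3 (2.03 ± 0.10) and DDIT4 (2.19 ± 0.13), and ASNS at 0.49 ± 0.10. The call of ASNS was lost without replicate 2 of HCT116 WT cells with glutamine (adjusted p = 0.0515) or replicate 1 without it (adjusted p = 0.0647). All 29 DNA replication genes and 20 of 24 mitosis genes fell (adjusted p = 1.44e-32 and 2.88e-19; 29 and 24 adjusted over the list alone). Among them were cyclin A2, CCNA2 (-0.98 ± 0.07), the checkpoint kinases TTK (-1.29 ± 0.10) and BUB1 (-1.02 ± 0.08) and the helicase subunit MCM2 (-1.47 ± 0.08). With an estimated correlation the adjusted p was 0.000527 for the amino acid response, 8.55e-05 for DNA replication and 0.00308 for mitosis. In all 3189 genes passed (1611 rose, 1578 fell), as few as 2054 with 1 array left out and 2070 with HCT116 fitted alone. In the other derivatives mitosis genes fell in 15 cases in DLD1 Mut cells (adjusted p = 4.45e-05, and adjusted p = 0.0957 with an estimated correlation) and in 6 in DLD1 WT cells, where the list was not called (adjusted p = 0.191).

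The response of DLD1 was then set against that of HCT116, averaged over the genotypes. ASNS had a higher change in DLD1, by a log2 difference of 1.83 ± 0.10 (adjusted p = 9.84e-06), as did PHGDH (1.54 ± 0.09), PSAT1 (1.13 ± 0.09) and TXNIP (2.49 ± 0.25). In HCT116 ASNS fell in Mut and rose in WT cells, and PHGDH and PSAT1 fell in Mut cells. In the amino acid response list 24 genes had a higher change in DLD1 and 1, the secreted hormone STC2 (-1.77 ± 0.39), a lower one (adjusted p = 1.75e-11; 27 and 2 adjusted over the list alone). The same direction was called for aminoacyl-tRNA synthetases (10 higher, 1 lower of 19, adjusted p = 1.59e-06), with NARS1 (0.85 ± 0.08) and WARS1 (0.85 ± 0.10) among them. It was also called for serine and one-carbon genes (8 higher of 14, adjusted p = 3.18e-06) and for DNA replication (17 higher, 1 lower, adjusted p = 3.21e-08). Wnt targets changed the other way (9 lower, 1 higher, adjusted p = 6.45e-06), such as ASCL2 (-2.33 ± 0.20) and CD44 (-1.61 ± 0.16). With the mean of its probe sets in place of the brightest, CD44 had a difference of -0.18 and was not called (adjusted p = 0.430). With an estimated correlation the adjusted p was 0.00188, 0.00649, 0.00592, 0.00592 and 0.00987 in this order. SLAMF6 (-4.04 ± 0.30) and KIT (-2.88 ± 0.30) had lower changes in DLD1. SLAMF6 was not among the genes above the median of mean level, and whether its level in HCT116 left room for a fall was not tested. In all 2973 genes differed (1573 higher in DLD1, 1400 lower).

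The comparisons of Mut with WT cells in glutamine ask what the remaining PIK3CA allele goes with when glutamine is present, although each genotype of a line is a single derivative. In both lines Mut cells had higher levels of amino acid response genes with glutamine present. DDIT4 was 6.62-fold higher in DLD1 Mut than WT cells (2.73 ± 0.13, adjusted p = 1.09e-06) and 2.98-fold higher in HCT116 (1.58 ± 0.13, adjusted p = 0.000163), and the glutathione-degrading enzyme CHAC1 was higher in DLD1 (1.83 ± 0.12) and HCT116 (1.49 ± 0.12). ASNS was higher in DLD1 (0.87 ± 0.10) and HCT116 Mut cells (0.71 ± 0.10), as was PHGDH (1.18 ± 0.09 and 0.75 ± 0.09). Of 36 members of the list 16 were higher in DLD1 and 13 in HCT116 Mut cells and none was lower (adjusted p = 1.55e-14 and 2.78e-17). Adjusted over the list alone, 19 and 22 were higher. Aminoacyl-tRNA synthetases were higher in 7 and 3 of 19 cases and lower in 1 and 0 (adjusted p = 2.66e-06 and 1.02e-06; 12 and 11 higher adjusted over the list alone), such as AARS1 (0.66 ± 0.09) in DLD1. Serine and one-carbon genes, a list that shares 6 symbols with the amino acid response list, were higher in 6 and 4 of 14 cases (adjusted p = 0.00353 and 0.000229). With an estimated correlation the adjusted p in DLD1 and HCT116 was 0.000799 and 0.000421, 0.0125 and 0.011, and 0.0459 and 0.0162 for these lists. Cholesterol synthesis genes were lower in HCT116 Mut cells in 10 of 18 cases (adjusted p = 3.64e-16, and 0.0112 with an estimated correlation), such as MSMO1 (-0.98 ± 0.12) and INSIG1 (-1.39 ± 0.17). With HCT116 fitted alone ASNS (adjusted p = 0.0606) and INSIG1 (adjusted p = 0.0561) lost these calls.

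Other large differences with glutamine are given by line, and whether they differ between the lines was not tested. In DLD1 the colon differentiation keratin KRT20 (-6.96 ± 0.24), the galactolipid enzyme UGT8 (-6.21 ± 0.13), the TEAD cofactor VGLL1 (-5.77 ± 0.20), the nuclear receptor corepressor NRIP1 (-5.14 ± 0.13) and the gluconeogenic enzyme FBP1 (-4.85 ± 0.30) were lower in Mut cells. Higher there were KLHL4 (4.66 ± 0.17), the sialomucin PODXL2 (4.65 ± 0.29), the growth factor ANGPT1 (3.85 ± 0.21) and the translation elongation factor EEF1A2 (3.74 ± 0.13). In HCT116 the O-glycosylation enzyme GALNT5 (-3.74 ± 0.22) and the guidance ligand SEMA3A (-2.97 ± 0.25) were lower, and the cytoskeletal protein DPYSL3 (2.81 ± 0.24), the hexokinase-like HKDC1 (2.71 ± 0.27), the NMDA receptor subunit GRIN2B (2.65 ± 0.20) and UPP1 (2.16 ± 0.23) were higher. FBP1, KLHL4, PODXL2, ANGPT1 and HKDC1 were not among the genes above the median of mean level. Whether background limits the size of their differences was not tested. In DLD1 910 genes differed (408 higher in Mut, 502 lower), in HCT116 507 (175 higher, 332 lower) and on average over the lines 1098 (447 higher, 651 lower). With 1 array left out these counts fell to as few as 459, 199 and 583, and with each line fitted separately to 599 in DLD1 and 89 in HCT116. With trend and robust in eBayes they rose to 1379, 963 and 1648. Between the lines 30 genes were higher and 44 lower in Mut cells of both, and 24 differed in opposite directions. Independent calls would give 4.56 higher and 10.6 lower in both (Fisher's exact test, two-sided, p = 1.69e-16 and 9.42e-16, with genes treated as independent). The calls of the lines are not independent, since both use the same spread of each gene. Across genes the differences of the lines correlated at only r = 0.09. Of the 910 genes called in DLD1, 530 had the same sign in HCT116. The 74 shared genes fell to as few as 36 with 1 array left out and to 16 with each line fitted separately, were 45 with no filter, and rose to 115 above the median of mean level and 165 with trend and robust. Shared genes included GALNT5, DDIT4, CHAC1, NETO2 (1.53 ± 0.07), an auxiliary subunit of glutamate receptors, SAMD9 (-1.85 ± 0.13), an interferon-induced protein, the lysine catabolism enzyme AASS (-1.49 ± 0.15), the glucose transporter SLC2A12 (-1.33 ± 0.13) and perforin, PRF1 (-1.43 ± 0.15).

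Without glutamine the amino acid response list was not called between the genotypes (adjusted p = 0.544 in DLD1 and 0.27 in HCT116). In DLD1 3 of its genes were higher in Mut cells, with NUPR1 (2.49 ± 0.22), a stress-induced chromatin protein, the largest difference, and 3 were lower, such as the mitochondrial enzyme PCK2 (-0.94 ± 0.16). In HCT116 6 were higher, with PPP1R15A (1.25 ± 0.11), and 11 lower, such as PHGDH (-0.87 ± 0.09). ASNS did not pass in DLD1 (-0.25 ± 0.10, adjusted p = 0.169) and was lower in HCT116 Mut cells (-0.49 ± 0.10), a call lost without replicate 1 of HCT116 WT cells without glutamine (adjusted p = 0.0594). DNA replication genes were lower in DLD1 Mut cells in 17 of 29 cases (adjusted p = 5.14e-13, and 0.00257 with an estimated correlation; 21 adjusted over the list alone), among them the licensing factor CDC6 (-0.94 ± 0.09) and MCM3 (-0.82 ± 0.09). Mitosis genes were higher in HCT116 Mut cells in 22 of 24 cases (median 0.82, adjusted p = 1e-16, and 0.0163 with an estimated correlation), such as UBE2C (1.20 ± 0.09) and topoisomerase, TOP2A (1.14 ± 0.09). Large differences were those of KLHL4 (4.98 ± 0.17), VGLL1 (-6.11 ± 0.20) and KRT20 (-5.57 ± 0.24) in DLD1 and SNAI2 (5.24 ± 0.25), WNT16 (-3.93 ± 0.34) and GALNT5 (-3.54 ± 0.22) in HCT116. In DLD1 1610 genes differed (683 higher in Mut, 927 lower; 42.4% higher, against 54.1% with each array shifted to the same median) and in HCT116 3858 (1922 higher, 1936 lower). The DLD1 count fell to as few as 709 with 1 array left out.

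The interaction asks whether the response to withdrawal differed between Mut and WT cells of a line. In both lines the change of amino acid response genes was lower in Mut cells. In DLD1 Mut cells the list still rose, while in HCT116 Mut cells it was not called and ASNS and PHGDH fell. The change of DDIT4 was lower by a log2 difference of -2.40 ± 0.19 in DLD1 (adjusted p = 0.000777) and -1.75 ± 0.19 in HCT116 (adjusted p = 0.000661). The differences in DLD1 and HCT116 were -1.94 ± 0.17 and -2.21 ± 0.17 for CHAC1, -1.30 ± 0.13 and -1.62 ± 0.13 for PHGDH, and -1.12 ± 0.15 and -1.20 ± 0.15 for ASNS. Mean log2 intensities of ASNS (± SD, n = 2 arrays) were 6.18 ± 0.10 with and 8.46 ± 0.09 without glutamine in DLD1 WT and 7.04 ± 0.11 and 8.21 ± 0.01 in DLD1 Mut cells. In the same order they were 7.52 ± 0.04 and 8.01 ± 0.14 in HCT116 WT and 8.24 ± 0.10 and 7.53 ± 0.01 in HCT116 Mut cells. Of 36 members of the list 13 had a lower change in DLD1 Mut cells and 0 a higher one (median -0.57, adjusted p = 2.67e-13). In HCT116 Mut cells 13 had a lower and 1 a higher change (median -0.58, adjusted p = 8.28e-09). Adjusted over the list alone, 21 and 16 were lower. The calls held with an estimated correlation (adjusted p = 0.0006 and 0.00316). In DLD1 the call of ASNS was lost without replicate 1 of Mut or WT cells with glutamine, replicate 1 or 2 of Mut cells without it or replicate 2 of WT cells without it (adjusted p from 0.0501 to 0.0601), or with a replicate block within each line (adjusted p = 0.0523). With DLD1 fitted alone DDIT4 (adjusted p = 0.0682), PHGDH (adjusted p = 0.0944) and ASNS (adjusted p = 0.0980) lost it. The member with a higher change in HCT116 was PPP1R15A (0.83 ± 0.16, adjusted p = 0.00962, and 0.0594 with HCT116 fitted alone). Serine and one-carbon genes had lower changes in Mut cells in 5 of 14 cases in DLD1 (adjusted p = 1.52e-07, and 0.00265 with an estimated correlation) and 5 in HCT116 (adjusted p = 0.0114, and adjusted p = 0.0607 with an estimated correlation).

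**Figure D2:**
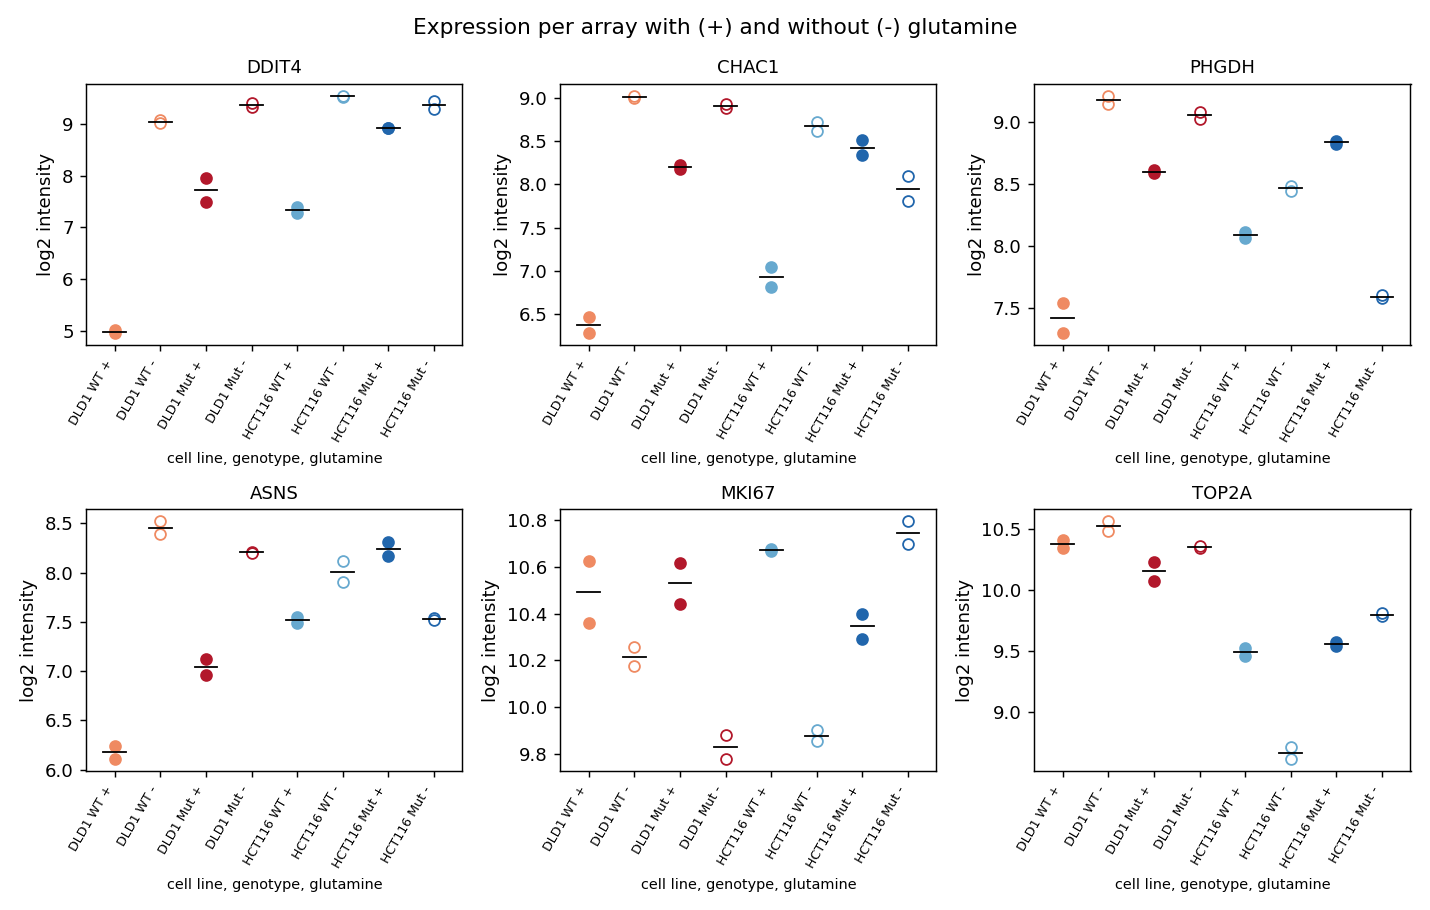
Log2 intensity (y axis) of DDIT4, CHAC1, PHGDH, ASNS, MKI67 and TOP2A on each array, by cell line, genotype and glutamine (x axis), with filled points for arrays with and open points for arrays without glutamine and a line at each group's mean of 2 arrays. ASNS means were 6.18 ± 0.10 with and 8.46 ± 0.09 without glutamine in DLD1 WT cells (± SD).

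Further interactions are given by line, and their difference between the lines was not tested. In DLD1 DNA replication genes fell further in Mut than in WT cells, with 8 of 29 called (median -0.51, adjusted p = 4.1e-19, and 0.0006 with an estimated correlation; 23 adjusted over the list alone). Among them was MCM3 (-0.90 ± 0.13), whose call was lost without any single DLD1 array except replicate 2 of Mut cells with glutamine (adjusted p from 0.0501 to 0.0951). The call of MCM3 was also lost with a replicate block within each line (adjusted p = 0.0569) and with DLD1 fitted alone (adjusted p = 0.120). The membrane-shaping ATPase EHD2 (-2.19 ± 0.25) also had a lower change, and the serine protease TMPRSS11F (3.10 ± 0.19) and NRIP1 (2.13 ± 0.19) higher ones, of which EHD2 (adjusted p = 0.0980) and NRIP1 (adjusted p = 0.0762) lost the call with DLD1 fitted alone. TMPRSS11F was not among the genes above the median of mean level. In HCT116 mitosis genes fell as a list in WT cells and were not called as a list in Mut cells (adjusted p = 0.903). The difference between them was called for 18 of 24 (median 0.80, adjusted p = 2.24e-18, and 0.00456 with an estimated correlation; 21 adjusted over the list alone). Examples are the cytokinesis protein ANLN (1.25 ± 0.12), the proliferation marker MKI67 (1.20 ± 0.15) and TOP2A (1.07 ± 0.12). Also in HCT116, 8 of 20 p53 targets had higher changes in Mut cells and 1 a lower one (adjusted p = 1.57e-05, and 0.0229 with an estimated correlation), such as the nuclease AEN (1.81 ± 0.22). Of 19 NRF2 targets 9 had lower ones (adjusted p = 9.99e-08, and 0.00316 with an estimated correlation), such as GSR (-1.36 ± 0.12). Aminoacyl-tRNA synthetases had lower changes in HCT116 Mut cells in 8 of 19 cases (adjusted p = 6.7e-06, and 0.00912 with an estimated correlation) and in DLD1 Mut cells in 1 (adjusted p = 0.00394, and adjusted p = 0.0574 with an estimated correlation). SNAI2 (4.80 ± 0.36), the lipase LIPG (3.65 ± 0.34) and the matricellular protein CCN1 (2.84 ± 0.23) had the largest differences in HCT116 among the genes named here, and BMP4 (-2.10 ± 0.12) and WNT16 (-2.53 ± 0.48) had lower changes. Averaged over the lines DDIT4 (-2.08 ± 0.13), CHAC1 (-2.07 ± 0.12) and PHGDH (-1.46 ± 0.09) had lower and SNAI2 (2.68 ± 0.25) a higher change in Mut cells. The average of SNAI2 rests mostly on HCT116, where it was 4.80. The interaction was called for 129 genes in DLD1 (40 higher, 89 lower; 31.0% higher, against 55.6% with each array shifted to the same median), 1488 in HCT116 (744 higher, 744 lower) and 1282 on average (608 higher, 674 lower; 47.4% higher, against 58.2% with that shift). In both lines 8 genes were called higher and 31 lower, where independent calls would give 1.90 and 4.22, and 8 were called in opposite directions. With 1 array left out the DLD1 count lay between 15 and 97, and with DLD1 fitted alone it was 3, so the DLD1 count depends on the arrays in the fit. It depends on the filter and model too, with 46 genes with no filter, 328 above the median of mean level, 22 with a replicate block within each line, 76 with a block over all arrays and 602 with trend and robust in eBayes. The HCT116 and average counts fell to as few as 842 and 801 with 1 array left out, and the HCT116 count to 430 with HCT116 fitted alone, and with trend and robust the average count rose to 2027; the closing section names each array.

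**Figure D3:**
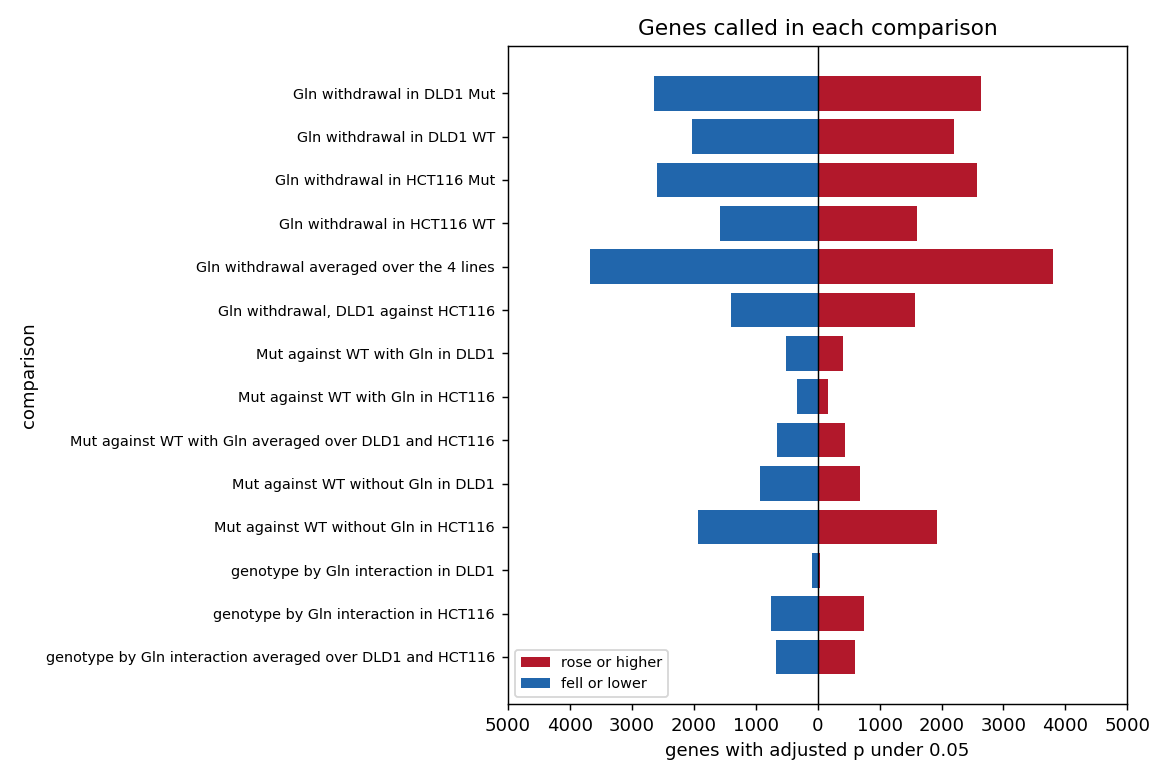
Number of genes with adjusted p under 0.05 (x axis) in each of the 14 comparisons (y axis), with genes that rose or were higher to the right of 0 and genes that fell or were lower to the left. Glutamine withdrawal gave between 3189 calls in HCT116 WT and 5268 in DLD1 Mut cells, and the interaction 129 in DLD1 and 1488 in HCT116.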

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

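Of the tests in this part, only those of exchanged labels on genes that differ 2-fold or more and on the size of the change were chosen after a result had been seen, and the limits of the others were set after the list values and before those tests were run. The results here were picked out because a test of the difference between groups itself passed: between Mut and WT cells in their response to glutamine withdrawal, or between DLD1 and HCT116. The interaction was called for 129 genes in DLD1, 1488 in HCT116 and 1282 on average, and the response differed between the lines for 2973.

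Lists singled out in the DLD1 interaction had medians of -0.57 (the amino acid response), -0.63 (serine and one-carbon genes) and -0.51 (DNA replication). In HCT116 the medians were -0.58 (the amino acid response), -0.39 (aminoacyl-tRNA synthetases), 0.80 (mitosis), 0.58 (p53 targets) and -0.67 (NRF2 targets). Averaged over the lines they were -0.52 (the amino acid response), -0.25 (aminoacyl-tRNA synthetases), -0.29 (serine and one-carbon genes) and -0.34 (NRF2 targets). Between DLD1 and HCT116 the lists whose responses differed had median differences of 0.57 (the amino acid response), 0.39 (aminoacyl-tRNA synthetases), 0.51 (serine and one-carbon genes), 0.37 (DNA replication) and -0.86 (Wnt targets). Genes named above with a DLD1 interaction were ASNS (-1.12), CHAC1 (-1.94), DDIT4 (-2.40), EHD2 (-2.19), MCM3 (-0.90), NRIP1 (2.13), PHGDH (-1.30) and TMPRSS11F (3.10). Those with an HCT116 interaction were AEN (1.81), ANLN (1.25), ASNS (-1.20), BMP4 (-2.10), CCN1 (2.84), CHAC1 (-2.21), DDIT4 (-1.75), GSR (-1.36), LIPG (3.65), MKI67 (1.20), PHGDH (-1.62), PPP1R15A (0.83), SNAI2 (4.80), TOP2A (1.07) and WNT16 (-2.53). On average over the lines these were CHAC1 (-2.07), DDIT4 (-2.08), PHGDH (-1.46) and SNAI2 (2.68). Genes whose response differed between DLD1 and HCT116 were ASCL2 (-2.33), ASNS (1.83), CD44 (-1.61), KIT (-2.88), NARS1 (0.85), PHGDH (1.54), PSAT1 (1.13), SLAMF6 (-4.04), STC2 (-1.77), TXNIP (2.49) and WARS1 (0.85). Outside the data of the comparisons, 13229 of the 29746 probe sets with no symbol or several were bright enough to test, and 2471 of them changed on average over the 4 derivatives on glutamine withdrawal (1093 rose, 1378 fell), 2041 with no symbol and 430 with several.

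Amino acid response genes had a lower change on glutamine withdrawal in Mut than in WT cells, with a median interaction of -0.52 averaged over the lines. A single aberrant array, normalization between arrays or compression of bright signals would bring this median above -0.25, but its value nearest 0 was -0.47 with 1 array left out and -0.48 under quantile normalization or a shift to the same median, and it was -0.58 for the 18 members of lower level, where compression is least. The tables thus argue against a single aberrant array and against compression of bright signals. Array medians already lay between 1.83 and 1.89 on the log2 scale, so scaling the arrays again could move the list median only little. It does not test any normalization applied before deposit, and that explanation stays open. The median lay below 0 in 2 of 2 lines, but each genotype of a line is 1 derivative, so PIK3CA genotype and chance differences between derivatives cannot be told apart. The interaction is the Mut to WT difference without glutamine less that with it, and the list was higher in Mut cells with glutamine and not called without it.

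Mitosis genes fell on glutamine withdrawal in HCT116 WT cells. The lowest value of their median HCT116 interaction (0.80) was 0.76 with 1 array left out and 0.80 under the other normalizations. Both values lay above the limit of 0.4 set for these explanations, and the first argues against a single aberrant array. The other normalizations could again move the median only little, so they do not test any normalization applied before deposit. Had the Mut and WT labels been exchanged in the HCT116 arrays without glutamine, under 50% of the genes that differ with glutamine would keep their sign without it. In the data 396 of 507 (78.1%) kept it, just under the limit of 80% set for exclusion. In a later test 115 of 138 genes that differ 2-fold or more (83.3%) kept it, which argues against an exchange for these genes. Over all 507 the change without glutamine, in the direction seen with it, had a median of 0.45 and a lower quartile of 0.077. A lower quartile above 0 follows from the 78.1% that kept their sign, so it adds no further test. In DLD1 the list was called as falling in Mut cells, at the preset correlation only, and was not called in WT cells. The pattern of HCT116 was thus not seen in the DLD1 pair. A difference of cell density or growth between the cultures was not tested, and in HCT116 PIK3CA genotype stays open beside differences of single derivatives.

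Other splits of the arrays were counted in models with additive terms, so their real values differ from the counts above. For glutamine withdrawal on average the real split called 6178 genes and the highest other 2957, with 1 of 100 splits as large. The highest other follows glutamine on 14 of 16 arrays, and 96 of the others called none. A split that does not follow glutamine leaves the glutamine effect in the spread, which lowers its count. Thus no other split drawn called as many genes, but their low counts do not measure chance. For the difference between the lines the real split called 1533 and the highest other 3524, with 2 of 100 as large. The model had no term for the line apart from the split, so other splits left the difference between the lines in the spread. Of those others 95 called none, and this count decides nothing about chance. That highest split follows the line on only 8 of 16 arrays, and glutamine, genotype by glutamine and line by glutamine on 12 each. The next called 1240 genes and follows the line on 12. What raised these counts was not tested. Mut against WT with glutamine on average called 23 genes in the real split and 5820 in the split that follows the cell line, and the other 33 of the 35 splits called none. The split by cell line was fitted without a term for the line and alone kept the share from falling under 5%, so this count decides nothing about chance. The interaction on average called 236 in the real split and 785 in the highest other, with 2 of 100 as large. Here the model had no term for genotype apart from the split, so this count decides nothing about chance either. The highest other split follows genotype and glutamine on 12 of 16 arrays each, and what raised its count was not tested.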

How the results depend on the processing

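Every alternative in this part was chosen before the data were examined, and no called result changed its direction under any of them. Quantile normalization, a shift of each array to the same median and the mean of a gene's probe sets moved none of the 16 counts of genes by over 1.5 times. The share of higher calls moved by over 10 points with the shift to the same median: from 42.4% to 54.1% for Mut against WT without glutamine in DLD1, from 31.0% to 55.6% for the interaction in DLD1 and from 47.4% to 58.2% for the interaction on average. Other scaling left it within 10 points. A 2-fold minimum lowers every count by construction. For withdrawal in DLD1 Mut, DLD1 WT, HCT116 Mut and HCT116 WT, on average, and in DLD1 against HCT116 it left 1281, 899, 1226, 566, 535 and 508. For Mut against WT with glutamine in DLD1, in HCT116 and on average it left 297, 138 and 105, and without glutamine in DLD1 and HCT116 345 and 755. For the interaction in DLD1, in HCT116 and on average it left 63, 517 and 138, of genes shared by the 4 derivatives 101 and of Mut against WT genes shared by the lines 11. With no filter on dim genes the count was 46 for the interaction in DLD1 (against 129) and 45 for Mut against WT genes shared by the lines (against 74). Above the median of mean level it was 328 for the interaction in DLD1 (against 129) and 115 for Mut against WT genes shared by the lines (against 74). These alternatives test more and fewer genes. With trend and robust in eBayes it was 1379 for Mut against WT with glutamine in DLD1 (against 910), 963 for Mut against WT with glutamine in HCT116 (against 507) and 1648 for Mut against WT with glutamine on average (against 1098). It gave 602 for the interaction in DLD1 (against 129), 2027 for the interaction on average (against 1282) and 165 for Mut against WT genes shared by the lines (against 74). The cause was not tested. Each line fitted separately, with fewer arrays for the spread, gave 599 for Mut against WT with glutamine in DLD1 (against 910), 3 for the interaction in DLD1 (against 129) and 2070 for withdrawal in HCT116 WT (against 3189). It gave 89 for Mut against WT with glutamine in HCT116 (against 507), 430 for the interaction in HCT116 (against 1488), 713 for genes shared by the 4 derivatives (against 1131) and 16 for Mut against WT genes shared by the lines (against 74). Arrays with the same replicate number did not deviate together (28 pairs of groups, correlations from -0.04 to 0.03), so the numbers were not taken as pairs. A replicate block over all arrays gave 76 genes for the interaction in DLD1 and a block within each line 22, against 129, and the other 15 counts moved by 1.5 times or less. The cause was not tested. Leaving out 1 array leaves an arm of 1, which limma assumes to vary like the other groups. Arrays whose loss moved a count by over 1.5 times follow with their replicate numbers (+Gln with, -Gln without glutamine) and, in parentheses, the counts without them. Withdrawal in HCT116 WT ranged from 2054 to 3140 (against 3189). The arrays were HCT116 WT +Gln 1 and 2 (2109 and 2054) and HCT116 WT -Gln 1 (2120). Mut against WT +Gln in DLD1 ranged from 459 to 887 (against 910). The arrays were DLD1 Mut +Gln 1 and 2 (459 and 466) and DLD1 WT +Gln 2 (462). Mut against WT +Gln in HCT116 ranged from 199 to 488 (against 507). The arrays were HCT116 Mut +Gln 2 (199) and HCT116 WT +Gln 1 and 2 (200 and 203). Mut against WT +Gln on average ranged from 583 to 1006 (against 1098). The arrays were DLD1 Mut +Gln 1 and 2 (600 and 629), DLD1 WT +Gln 2 (583), HCT116 Mut +Gln 2 (680) and HCT116 WT +Gln 1 and 2 (592 and 677). Mut against WT without glutamine in DLD1 ranged from 709 to 1563 (against 1610). The arrays were DLD1 Mut -Gln 1 and 2 (769 and 849) and DLD1 WT -Gln 1 and 2 (709 and 823). The interaction in DLD1 ranged from 15 to 97 (against 129). The arrays were DLD1 Mut +Gln 1 and 2 (26 and 34), DLD1 WT +Gln 1 and 2 (24 and 36), DLD1 Mut -Gln 1 and 2 (26 and 25), DLD1 WT -Gln 1 and 2 (25 and 15) and HCT116 WT +Gln 1 and 2 (63 and 63). The interaction in HCT116 ranged from 842 to 1396 (against 1488). The arrays were HCT116 WT +Gln 1 and 2 (912 and 926), HCT116 Mut -Gln 2 (842) and HCT116 WT -Gln 1 and 2 (961 and 977). The interaction on average ranged from 801 to 1042 (against 1282). The arrays were DLD1 WT -Gln 1 and 2 (801 and 829) and HCT116 WT +Gln 1 (850). Mut against WT genes shared by the lines ranged from 36 to 71 (against 74). The arrays were DLD1 Mut +Gln 1 and 2 (42 and 37), DLD1 WT +Gln 2 (37), HCT116 Mut +Gln 2 (38) and HCT116 WT +Gln 1 and 2 (38 and 36). The other 7 counts did not move so far without any 1 array. Of the genes named, in their contrasts, 10 lost their call with each line fitted separately and 123 did not. With 1 array left out 18 of the gene values lost it, 3 gained it and 3067 did neither, and the changed ones were of GLUL, ASNS and MCM3. Among 336 list tests 77 lost their call with an estimated correlation and none gained one. The test fry called 88 more and lost 2. With 1 array left out 86 were lost, 32 gained and 5258 did not change. Probe sets under a mean log2 intensity of 1.65 were too dim to be tested.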

Other observations

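Of the tests in this part, only that on the size of the DLD1 change without glutamine was chosen after a result had been seen, and the patterns were picked after the lists had been examined. Averaged over the 4 derivatives, glutamine withdrawal lowered genes of biosynthesis and energy metabolism that are not described above. Ribosome biogenesis genes fell in 17 of 21 cases (adjusted p = 1.55e-07, and 0.0391 with an estimated correlation), with the rRNA processing factor BOP1 (-1.16 ± 0.06) and the nucleolar protein MYBBP1A (-0.98 ± 0.05). Respiratory chain genes fell in 13 of 21 (adjusted p = 0.000236, and 0.0319 with an estimated correlation), with the complex I subunits NDUFA9 (-0.61 ± 0.04) and NDUFS3 (-0.57 ± 0.05). With the mean of its probe sets NDUFA9 had a log2 change of -0.30. Fatty acid synthesis genes fell in 9 of 12 cases and 1 rose (adjusted p = 0.000163, and adjusted p = 0.0569 with an estimated correlation), with the desaturase SCD (-1.47 ± 0.05) and fatty acid synthase, FASN (-1.38 ± 0.05). Hypoxia and glycolysis genes fell in 13 of 24 and rose in 4 (adjusted p = 0.0102, and adjusted p = 0.152 with an estimated correlation). They included lower LDHA (-0.68 ± 0.05) and GPI (-1.16 ± 0.06), both of glycolysis, and higher VEGFA (1.10 ± 0.06), an angiogenic factor. Wnt targets fell in 13 of 16 (adjusted p = 0.000144, and 0.0253 with an estimated correlation). FOXO targets rose in 14 of 22 and fell in 4 (adjusted p = 0.00138, and adjusted p = 0.143 with an estimated correlation), with the insulin receptor substrate IRS2 (1.58 ± 0.09) and the zinc finger factor KLF6 (1.47 ± 0.08). Lysosome and autophagy genes rose in 14 of 25 and fell in 6 (adjusted p = 0.0317, and adjusted p = 0.152 with an estimated correlation), with the autophagosome protein MAP1LC3B (1.73 ± 0.08) and the cargo receptor SQSTM1 (0.74 ± 0.05). p53 targets rose in 13 of 20 and fell in 2 (adjusted p = 0.00244, and adjusted p = 0.0602 with an estimated correlation).

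In single derivatives, endoplasmic reticulum chaperones fell in 11 of 18 cases and rose in 3 in DLD1 WT cells (adjusted p = 0.000471, and adjusted p = 0.172 with an estimated correlation), with PDIA4 (-1.13 ± 0.10) and CALR (-0.75 ± 0.08). Colon differentiation genes fell there in 6 of 18 cases (adjusted p = 0.022, adjusted p = 0.0629 with an estimated correlation and adjusted p = 0.0685 above the median of mean level), with the intestinal transcription factor CDX2 (-1.20 ± 0.10) and KRT20 (-1.50 ± 0.24). Aminoacyl-tRNA synthetases rose in 12 of 19 cases and fell in 4 in DLD1 WT cells (adjusted p = 0.00116, and 0.0307 with an estimated correlation). In HCT116 Mut cells 11 fell and 2 rose (adjusted p = 0.00357, and 0.0482 with an estimated correlation). Serine and one-carbon genes rose in 8 of 14 cases and fell in 3 in DLD1 WT cells (adjusted p = 0.0369, and adjusted p = 0.088 with an estimated correlation). That call was also lost with a replicate block within each line (adjusted p = 0.0525), with each line fitted separately (adjusted p = 0.0887) and above the median of mean level (adjusted p = 0.0737). These genes fell in 8 cases in HCT116 Mut cells (adjusted p = 3.01e-05, and 0.0101 with an estimated correlation). Also in HCT116 Mut cells, mesenchymal genes rose in 6 of 14 cases (median 0.08, mean 0.94, adjusted p = 0.0273, and adjusted p = 0.073 with an estimated correlation). They included SNAI2 and the matricellular proteins CCN1 (2.96 ± 0.17) and CCN2 (2.45 ± 0.18). NF-kB targets and chemokines rose in 6 of 14 cases and fell in 1 (adjusted p = 0.0341, and adjusted p = 0.0771 with an estimated correlation), with the NF-kB inhibitor TNFAIP3 (1.90 ± 0.21). Apoptosis regulators rose in 10 of 18 and fell in 3 (adjusted p = 0.0249, and adjusted p = 0.073 with an estimated correlation), with the pro-apoptotic BBC3 (1.51 ± 0.18) and the anti-apoptotic MCL1 (0.95 ± 0.11). Without HCT116 Mut replicate 1 with glutamine the mesenchymal (adjusted p = 0.0550) and NF-kB lists (adjusted p = 0.0683) lost their calls, and without replicate 1 without glutamine the apoptosis list did (adjusted p = 0.0621). With no filter on dim genes the NF-kB list lost it too (adjusted p = 0.0544). Interferon-stimulated genes were lower in DLD1 Mut than in WT cells without glutamine in 8 of 19 cases (adjusted p = 4.68e-06, and 0.042 with an estimated correlation), with IFI6 (-1.44 ± 0.11) and HERC5 (-1.99 ± 0.19). NRF2 targets were lower in HCT116 Mut cells without glutamine in 11 of 19 cases and higher in 1 (adjusted p = 7.98e-05, and 0.0163 with an estimated correlation), with the exporter ABCC2 (-1.55 ± 0.18).

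Of the 297 genes that differed by 2-fold or more between DLD1 Mut and WT cells with glutamine, KRT20 and KLHL4 among them, 296 had a place in the RefSeq gene table (GRCh38.p14). Neighbours were taken in the order of the 15511 tested genes with a place. Of the 296 genes 16 (5.40%) had such a gene of the same direction next to them on the chromosome. In 1000 shuffles of the gene order the median was 2.00% and the highest value 6.10% (permutation p = 0.0110). Gains or losses of chromosome segments in 1 derivative could give such an excess, but so could other causes of likeness between neighbours, which were not tested. Only adjacent genes that each differ 2-fold or more were counted, so the share of genes in such segments cannot be told. PIK3CA genotype and differences of single derivatives stay confounded. Without glutamine 225 of the 297 (75.8%) kept their direction with a log2 difference of 0.5 or more, between the limits of 50% and 80% set before. Over all 297 the change without glutamine, in the direction seen with it, had a median of 1.05 and a lower quartile of 0.53. A lower quartile above 0 follows from the 75.8%, so it adds no further test. Most of these genes thus differed without glutamine too, but the limit set for excluding the glutamine state at harvest was not reached.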
